A study of Arabidopsis thaliana with 12 samples.

How the data were processed

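RNA from anthers with their filaments of Arabidopsis thaliana was measured on 12 Affymetrix ATH1 arrays, which carry short oligonucleotide probes grouped into probe sets. Per the labels, 6 arrays came from a wild-type control and 6 from the ms35 mutant, with 2 arrays at each of 3 labelled stages of pollen development: pollen mitosis I (PMI), bicellular pollen and pollen mitosis II (PMII). The labels do not settle the background of the wild type: its source is named Glabra, the titles of its arrays name Ler, and the ms35 background is given as Ler-0. A difference between ms35 and wild type is therefore a difference between these lines, in probe set signal. Plants were grown at 22 °C with 22 h of daylight and 2 h of night, per the labels' protocols. The labels number the replicates 1 and 2 and do not say whether they came from separate plants, so p-values measure the spread between these samples, which may be technical.

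The deposited values are intensity on a linear scale, as signal per probe set. MAS5 and GCOS are named as the tools that made them, per the submitters' processing notes, and versions are not given in the sources used here. The values bear the mark of global scaling: the mean after trimming 2% of the values at each end was 99.96 or 99.97 on each array. Array medians differed, from 37.3 to 45.2, so the arrays had not been given equal quantiles. Between 13271 and 14470 probe sets per array lay above the low-signal limit used below. The number of arrays limits the precision. The ratio of 3' to 5' GAPDH control probe sets, a sign of RNA integrity, ran from 1.29 to 2.86, and was highest in wild type PMII replicate 2 (2.86), ms35 bicellular replicate 2 (2.37) and ms35 PMI replicate 2 (2.11).

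Of 22810 probe sets, 64 controls were left out. Log2(signal + 2.23) was computed from the remaining 22746, the pseudocount being the 10th percentile of all values, and a fold change on this scale understates the change of dim genes. Probe sets were tested if at least 2 arrays exceeded 25.5, the 40th percentile, which left 16464. Genes were named through the probe annotation provided with the series, updated by gene identifier to a gene table of assembly TAIR10.1 (used for names and for the order of loci only). That annotation gave 1 gene to 13513 probe sets, several to 503 and none to 8730, and 13436 of the single-gene probe sets matched the gene table. Probe sets with several genes were not named. MYB26, the gene affected in ms35, and NST1 and NST2 had no named probe set, so the check of the targeted gene was not analysed here.

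The model was limma 3.58.1 in R 4.3.3 with statmod 1.5.0: means of the 6 groups, all 12 arrays in 1 fit, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment with a threshold of 0.05. It had 6 residual degrees of freedom. Contrasts were the genotype effect averaged over stages and at each stage (ms35 minus wild type), the steps between successive labelled stages within each genotype, and the genotype by stage interaction (an F test). The design, the alternatives, 16 gene lists and the rule for named genes were fixed before the data were examined. The rule named MYB26, NST1 and NST2 first; per contrast, the 8 largest positive and the 8 largest negative log2 changes among single-gene probe sets past the threshold whose groups did not overlap (within any stage, for the averaged effect); for the interaction the 8 smallest p; and from each list up to 4 members past the threshold, or at most 2 as values. The text names fewer in that order. A gene with several probe sets was represented in its list by the one with the highest mean.

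Of 269 list members, 39 had a named probe set and 35 were tested. Lists with at least 3 tested members, 7 of the 16, were tested with camera (preset inter-gene correlation 0.01) in 8 contrasts. None of the 24 secondary wall regulators or the 27 jasmonate genes on the lists was named, and the defence list had no tested member. A further 28 gene families were defined from gene symbols after the annotation was seen and before any contrast was computed; 25 were tested.

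The alternatives were quantile normalization, median centring, other pseudocounts and filters, the replicate number as a block, other variance models, array weights, only the arrays compared, other thresholds, and leaving out each array; the closing section gives their effect. The fit was tested on simulated data with 100 probe sets changed by each of 2 sizes among 16464. For the averaged genotype effect it recovered 85% of those changed by 2 on the log2 scale and 61% of those changed by 1, with 13 false calls among 159. At a single stage it recovered 59% to 65% of changes of 2 and 10% to 15% of changes of 1. In camera, 6 of 200 unchanged lists gave p under 0.05. The simulated noise was independent between probe sets. These rates therefore leave out correlation between genes and may differ in the real arrays.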

Results

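The data set compared anthers of the ms35 mutant, in which the transcription factor MYB26 is affected and anthers do not open, with wild type, to identify genes downstream of MS35/MYB26. There were 6 groups of 2 arrays, from 2 genotypes at 3 labelled stages. Arrays of the same group correlated across probe sets with r between 0.899 and 0.937, and no pair held identical values. MYB26, NST1 and NST2 were to be given first in each array, and were not analysed here because no probe set carried their names. The first principal component (46.2% of the variance) ordered the arrays by labelled stage, with ms35 bicellular replicate 2 at -18.99 between the PMI and the other bicellular arrays, and the second (12.7%) separated the genotypes. Stage names are used as labelled, because marker genes given with the stage steps ran against the usual order of these stages.

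Averaged over the stages, IRX15-L, IRX15 and HCT were lower in ms35. IRX15-L, which acts in the synthesis of xylan in secondary cell walls, had a log2 fold change of -4.07 ± 0.45 (SE; limma adjusted p = 0.000191), and its homologue IRX15 fell by 2.54 ± 0.55 on the log2 scale (adjusted p = 0.0175). HCT, an enzyme of lignin synthesis, fell by 1.81 ± 0.14 (adjusted p = 1.23e-05), from a mean signal of 660 to 158 at the bicellular stage. AT3G13610, which encodes F6'H1, an enzyme of coumarin synthesis, fell by 4.70 ± 0.35 (adjusted p = 7.49e-06). Of the 3 tested members of the secondary wall cellulose and xylan list, 2 fell and none rose, and 3 passed when adjusted over the list alone; GUT2 had -0.84 ± 0.25 (adjusted p = 0.0757). Camera placed the list lower than other genes (adjusted p = 0.000464; adjusted p = 0.188 with an estimated correlation). IRX15 lost its call without wild type PMI replicate 1 (adjusted p = 0.0511), wild type PMI replicate 2 (0.0583) or wild type bicellular replicate 2 (0.0927), without a pseudocount (0.0534) and with a stricter filter (0.0574), and its adjusted p ran from 0.00365 to 0.0927 over the alternatives. HCT lies in a chromosome segment with an excess of genotype calls.

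**Figure D1:**
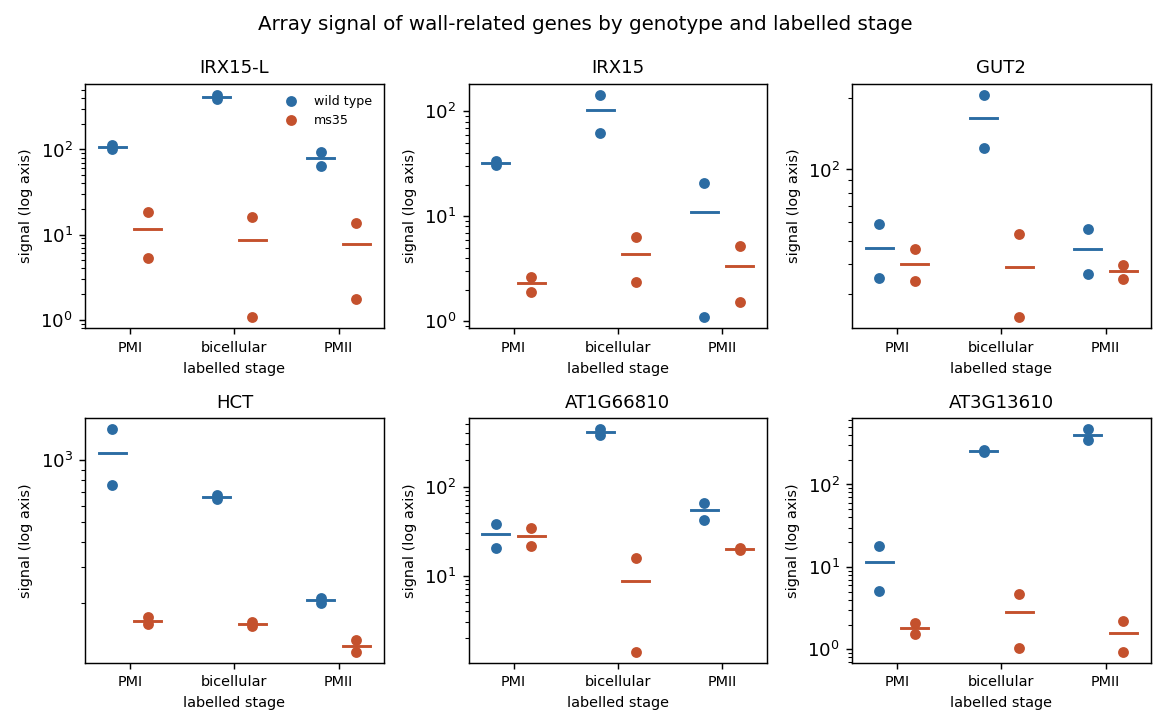
Signal on a log axis of 6 genes by labelled stage; each point is an array, each line the mean of 2 arrays, blue wild type and red ms35. The wild type arrays at the bicellular stage lie above those of ms35 in all 6 panels, for IRX15-L with means of 416 and 8.57.

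The averaged effect was called for 868 of 16464 probe sets, 369 higher and 499 lower in ms35 (limma, Benjamini-Hochberg). The largest decreases by the naming rule were AT2G27740, which fell by 5.45 ± 0.22 (adjusted p = 6.37e-08), and AT1G33700, which fell by 5.15 ± 0.26 (adjusted p = 3.43e-07). Both were near background in ms35: the mean signal of AT2G27740 at the bicellular stage was 1030 ± 65.6 (SD, n = 2) in wild type and 3.78 ± 1.68 (SD, n = 2) in ms35. AT1G24030 (-4.20 ± 0.33), AT3G58060 (-3.62 ± 0.46), AT5G39640 (-3.30 ± 0.40) and AT3G27200 (-3.17 ± 0.17) also fell, and AT1G24030 and AT3G58060 lie in segments with an excess of genotype calls. The largest increases by the naming rule were AT1G23960 (5.20 ± 0.45, adjusted p = 2.58e-05), AT1G50290 (4.01 ± 0.34), AT1G26710 (3.76 ± 0.29) and AT5G37130 (3.31 ± 0.31). Of these, AT1G23960 lies in such a segment. At all 3 stages, 20 probe sets were called higher and 17 lower. Averaged over the bicellular and PMII stages alone, a comparison chosen after seeing the data, 516 were called, 174 higher and 342 lower. With a 2-fold minimum 374 were called.

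The tested markers of late pollen, tapetum and green tissue were not called between genotypes on average. Most genes on these lists were not tested, so the lack of calls does not show equal shares of these cells. None of the 8 tested late pollen genes, of the 3 tapetum genes or of the 3 photosynthesis genes passed, nor did any pass when adjusted over the list alone (camera adjusted p = 0.769, 0.49 and 0.501). AGL104 had the largest difference among late pollen genes (0.60 ± 0.21, adjusted p = 0.150), and AT5G07230 among tapetum genes (0.65 ± 0.43, adjusted p = 0.483). Of 5 auxin genes, WES1, a GH3 enzyme that conjugates auxin, fell by 0.95 ± 0.18 (adjusted p = 0.00933; 1 passed adjusted over the list alone; camera adjusted p = 0.909). Without the variance trend its adjusted p was 0.0507, the highest of a range from 0.003. No member of the flavonoid list (3 tested) or the cell death list (3 tested) passed over all genes; 1 cell death gene passed adjusted over the list alone, and camera gave adjusted p = 0.909 and 0.187. The single tested members of the pollen coat, sperm cell, polygalacturonase and heat shock lists, AT1G75920 (0.30), MGH3 (0.32), ADPG1 (0.61) and ATHSP22.0 (-0.60), and both of the carpel and perianth list, INO (-0.21) and SPT (0.07), did not pass. AGL104, ADPG1 and INO lie in segments with an excess of genotype calls.

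In arrays labelled PMI, HCT fell by 2.64 ± 0.25 in ms35 (adjusted p = 0.000188) and LTI30, a dehydrin, fell by 6.01 ± 0.72 (adjusted p = 0.00124). ARPN, which encodes plantacyanin, rose by 4.18 ± 0.56 (adjusted p = 0.00221), and AT1G23960 rose by 5.33 ± 0.78 (adjusted p = 0.00376). No member of the secondary wall list passed, with -3.13 ± 0.78 for IRX15-L (adjusted p = 0.0678) and -2.93 ± 0.95 for IRX15 (adjusted p = 0.172), and 2 passed adjusted over the list alone; camera gave adjusted p = 0.0268 (adjusted p = 0.412 with an estimated correlation). The list no longer passed camera without wild type PMI replicate 1 (0.118) or ms35 PMI replicate 2 (0.0986), without a pseudocount (0.054) and with a stricter filter (0.0538), within a range from 0.00933. In all, 335 probe sets were called by limma, 165 higher and 170 lower. The count was 183 without wild type PMI replicate 1, 127 without its replicate 2, 161 without ms35 PMI replicate 1, 131 without its replicate 2 and 179 without the variance trend, and AT1G23960 lost its call without wild type PMI replicate 2 (adjusted p = 0.0521; 0.000122 to 0.0521 over the alternatives).

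At the bicellular stage, IRX15-L, GUT2 and HCT, the single tested gene of the lignin list, were lower in ms35. IRX15-L fell by 5.75 ± 0.78 (adjusted p = 0.0019), GUT2, which takes part in xylan synthesis, by 2.08 ± 0.43 (adjusted p = 0.0282) and HCT by 2.05 ± 0.25 (adjusted p = 0.000836), while IRX15 had -3.96 ± 0.95 (adjusted p = 0.0662). The effects on these genes were not found to differ between stages (interaction adjusted p = 0.637 for IRX15-L, 0.433 for GUT2, 0.104 for HCT and 0.657 for IRX15). AT1G66810, the zinc finger gene AtC3H14, fell by 5.66 ± 0.61 (adjusted p = 0.000375), from 408 to 8.59 in mean signal. AT2G27740 fell by 7.45 ± 0.37 (adjusted p = 1.80e-06) and AT3G13610 by 5.75 ± 0.60 (adjusted p = 0.000307). Of the 3 secondary wall list members, 2 fell, all 3 passed adjusted over the list alone, and camera gave adjusted p = 2.53e-05 (adjusted p = 0.160 with an estimated correlation). The late pollen list was higher in camera (adjusted p = 0.036; adjusted p = 0.574 with an estimated correlation), although none of its 8 members passed, over all genes or adjusted over the list alone. The array ms35 bicellular replicate 2, with a GAPDH ratio of 2.37, had a late pollen mean of 6.03 on the log2 scale against 4.84 in replicate 1 and 4.88 and 4.43 in wild type. Without it the late pollen list had adjusted p = 0.661, and without both arrays of highest GAPDH ratio 0.64. The list also did not pass without wild type bicellular replicate 2 (0.259), wild type PMI replicates 1 and 2 (0.0564 and 0.056) or ms35 PMI replicate 2 (0.0539) and with a stricter filter (0.0538), within a range from 0.00123. Limma called 291 probe sets, 66 higher and 225 lower, with 150 called without wild type bicellular replicate 1, 97 without its replicate 2 and 159 from the arrays compared alone. GUT2 lost its call without wild type bicellular replicate 1 (adjusted p = 0.0639), its replicate 2 (0.326) or ms35 bicellular replicate 1 (0.146), and without the variance trend (0.073), within a range from 0.0141 to 0.326.

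At the stage labelled PMII, AT2G05540 fell by 8.72 ± 0.94 (adjusted p = 0.000858), AT3G13610 by 6.75 ± 0.60 (adjusted p = 0.00016) and AT1G33700 by 6.21 ± 0.45 (adjusted p = 4.64e-05). AT1G26710 rose by 5.66 ± 0.51 (adjusted p = 0.00016). No secondary wall list member passed, and 1 passed adjusted over the list alone. HCT had -0.73 ± 0.25 (limma adjusted p = 0.253). It was the single tested gene of its list, so adjustment over the list alone left its p-value unadjusted, at under 0.05. Camera gave the secondary wall list adjusted p = 0.118, and 0.0449 without ms35 PMII replicate 2, the lowest of a range up to 0.437. Limma called 156 probe sets, 71 higher and 85 lower. The count was 97 without wild type PMII replicate 1, 45 without its replicate 2 (the array with the highest GAPDH ratio), 74 without ms35 PMII replicate 1, 75 without its replicate 2, 57 without the variance trend and 96 from the arrays compared alone.

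Called loci were not spread evenly over the genome. Over bins of 5000 locus numbers, 5 of 63 bins held more averaged-effect calls than other loci (Fisher's exact test, one-sided, Benjamini-Hochberg), with 30 of 198 loci called from AT1G20000 to AT1G24999 (15.2%) against 4.85% of 8998 loci overall. Of 1000 permutations of the calls, none gave as uneven a spread for the averaged effect, 9 did for the effect at PMI, 58 at bicellular and 18 at PMII, and 324 or more did for each stage step.

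**Figure D2:**
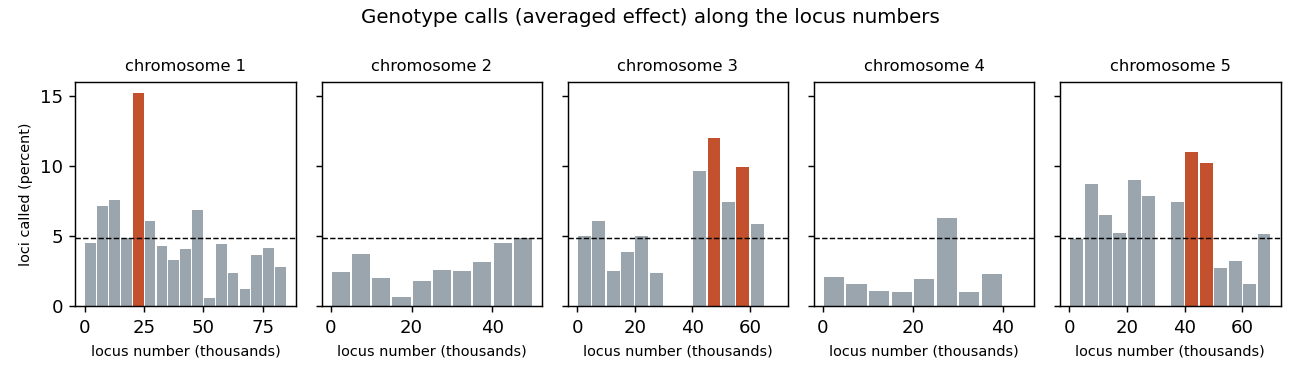
Percent of loci called for the averaged genotype effect per bin of 5000 locus numbers, by chromosome; red bars have an excess of calls, and the dashed line is the share over all loci (4.85%). The highest bar, on chromosome 1, reaches 15.2%.

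Calls at the separate stages came from 1 fit with a shared variance per probe set, so a probe set of low variance is called more easily at each stage. The numbers expected of independent lists, given here and for the steps below, leave this out and are not the numbers to be had without a shared effect. Between PMI and bicellular, 30 were higher in both (0.661 expected) and 65 lower in both (2.32 expected), with 2 in opposite directions. Between bicellular and PMII the numbers were 28 (0.285 expected) and 48 (1.16 expected), and between PMI and PMII 29 (0.712 expected) and 26 (0.878 expected). Genotype effects at different stages correlated across genes with r from 0.285 to 0.319; genes are not independent replicates.

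The genotype effect differed between stages for 32 probe sets (limma F test), 10 of them with 1 gene. Of those with 1 gene, AT3G27200 differed most (adjusted p = 0.00155). Its effect was -0.32 ± 0.30 at PMI, -5.64 ± 0.30 at bicellular and -3.54 ± 0.30 at PMII. AT3G06035 had 1.35 ± 0.24, -1.80 ± 0.24 and -0.62 ± 0.24 at the same stages (adjusted p = 0.00788). AT3G06035 lost its call without wild type bicellular replicate 2 (adjusted p = 0.0513) or ms35 PMI replicate 2 (0.0562) and without the variance trend (0.116), within a range from 0.00208, and AT3G27200 only without the variance trend (0.0611; range from 0.000143). None was called without the variance trend (limma; 1360 at an unadjusted p under 0.05). Without single arrays the count ran from 6, without wild type bicellular replicate 2, to 56, without ms35 bicellular replicate 1; it was 20, 17 and 19 without wild type PMI replicate 1, its replicate 2 and wild type bicellular replicate 1, 13 without wild type PMII replicate 1 or ms35 PMI replicate 1, 8 without wild type PMII replicate 2, 9 without ms35 PMI replicate 2 and 16 without ms35 PMII replicate 1.

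Between arrays labelled PMI and bicellular in wild type, genes of late pollen fell and genes of the tapetum, the layer that feeds the microspores, rose. ANX1, a pollen tube receptor kinase, fell by 4.48 ± 0.86 (adjusted p = 0.005), AT4G39110 fell by 3.78 ± 0.65 (adjusted p = 0.00296), and MGH3, a histone of the male germ line, fell by 2.33 ± 0.52 (adjusted p = 0.0104). SHT, a tapetal acyltransferase, rose by 6.15 ± 0.55 (adjusted p = 6.67e-05), and PRK, of the Calvin cycle, rose by 1.32 ± 0.25 (adjusted p = 0.00463). Of 8 late pollen genes 4 fell and none rose, and 7 passed adjusted over the list alone (camera adjusted p = 0.000132; adjusted p = 0.412 with an estimated correlation). Of 3 tapetum genes 2 rose, and 2 passed adjusted over the list alone (camera adjusted p = 0.0315; adjusted p = 0.412 with an estimated correlation). The tapetum list did not pass camera without wild type PMI replicate 2 (0.083) and with a stricter filter (0.0608), within a range from 0.0104. The secondary wall gene GUT2 rose by 1.76 ± 0.43 (adjusted p = 0.0145), the pollen coat gene AT1G75920 rose by 2.35 ± 0.29 and ADPG1, a polygalacturonase, fell from a mean signal of 255 to 21.3 (adjusted p = 0.00316). By the naming rule SBT4.13, a subtilase, fell most (-8.50 ± 0.94, adjusted p = 0.000211) and AT5G16960 rose most (6.95 ± 0.79, adjusted p = 0.000235). Limma called 2977 probe sets, 1776 higher and 1201 lower; the median of all tested probe sets shifted by 0.14, and with median centring 1303 were higher and 1425 lower. The count was 1686 without wild type PMI replicate 1, 1401 without its replicate 2, 1706 without wild type bicellular replicate 1 and 1056 without its replicate 2. Of the counted late pollen and tapetum genes, AGL65, ACT12 and AMS lost their calls in some settings. AGL65 lost it without either wild type PMI array (adjusted p = 0.0932 and 0.139), without either wild type bicellular array (0.0618 and 0.183) and without the variance trend (0.0501), within a range from 0.0176. ACT12 lost it without either wild type PMI array (0.112 and 0.05) or wild type bicellular replicate 2 (0.121), within a range from 0.0092. AMS lost it without wild type PMI replicate 2 (0.215), without either wild type bicellular array (0.0928 and 0.141) and without the variance trend (0.0525), within a range from 0.0106. ANX1 lost its call without wild type PMI replicate 1 (adjusted p = 0.052), MGH3 without that array (0.0758) or wild type bicellular replicate 2 (0.108), and GUT2 without the latter (0.145) or wild type PMI replicate 2 (0.114). Over the alternatives the adjusted p began at 0.00131 for ANX1, 0.00244 for MGH3 and 0.00767 for GUT2, and ended at these values.

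**Figure D3:**
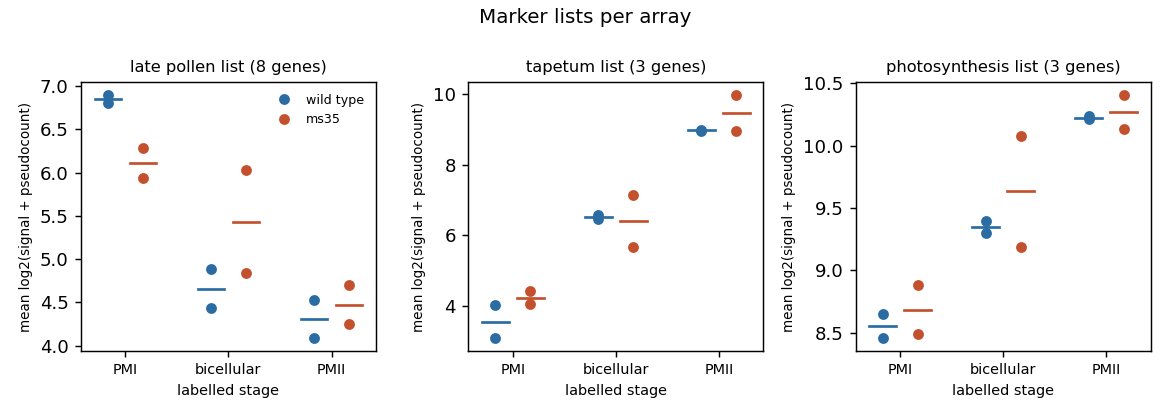
Mean log2(signal + pseudocount) per array of the late pollen, tapetum and photosynthesis lists by labelled stage; points are arrays, lines group means, blue wild type and red ms35. The late pollen mean was 6.90 and 6.80 in wild type arrays labelled PMI and 4.08 and 4.53 in those labelled PMII, while the tapetum mean went from 4.03 and 3.08 to 8.97 and 8.99.

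In ms35 the same step gave 434 calls by limma, 268 higher and 166 lower. SHT rose by 4.86 ± 0.55 (adjusted p = 0.00288), AT1G30020 by 4.47 ± 0.55 (adjusted p = 0.00316) and AT5G62080 by 3.57 ± 0.37 (adjusted p = 0.00198). No late pollen gene passed, over all genes or adjusted over the list alone (camera adjusted p = 0.0537, from 0.00722 to 0.493 over the alternatives). The late pollen mean was 6.03 in ms35 bicellular replicate 2 and 4.84 in replicate 1, against 5.94 and 6.29 in ms35 arrays labelled PMI, and without replicate 2 camera placed the list lower (adjusted p = 0.00722). It also did so without ms35 PMII replicates 1 and 2 (0.0366 and 0.0371) or wild type bicellular replicates 1 and 2 (0.0414 and 0.047), with a larger pseudocount (0.0381), without a filter (0.0432), with a stricter filter (0.0209) and without both arrays of highest GAPDH ratio (0.00886). Of 3 tapetum genes 1 rose, and 1 passed adjusted over the list alone (camera adjusted p = 0.0268; adjusted p = 0.412 with an estimated correlation). No photosynthesis gene passed over all genes and 3 passed adjusted over the list alone (camera adjusted p = 0.0118; adjusted p = 0.412 with an estimated correlation), and no auxin gene passed, with 2 adjusted over the list alone (camera adjusted p = 0.0356; adjusted p = 0.518 with an estimated correlation). Without ms35 bicellular replicate 1 none of these 3 lists passed camera (adjusted p = 0.132 for tapetum, 0.0815 for photosynthesis and 0.0762 for auxin). Without ms35 PMI replicate 2 the photosynthesis list had 0.0547 and the auxin list 0.237, and with a stricter filter the tapetum list had 0.0537 and the auxin list 0.0538. The auxin list had 0.0732 without ms35 bicellular replicate 2 and 0.0653 without both arrays of highest GAPDH ratio. Their ranges began at 0.00619, 0.00113 and 0.00889. Changes of this step correlated across genes between genotypes (r = 0.639), with 219 probe sets higher in both (28.9 expected), 131 lower in both (12.1 expected) and 1 opposite; the step itself differed between genotypes for 16 probe sets. With median centring 187 were higher and 190 lower. The count was 818 without ms35 bicellular replicate 2, 41 without its replicate 1, 33 without ms35 PMI replicate 2, 248 and 244 without wild type bicellular replicates 1 and 2, 245 with array weights, 111 without the variance trend and 1 from the arrays compared alone.

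Between arrays labelled bicellular and PMII in wild type, AT5G07230, a tapetum gene, rose by 5.29 ± 0.75 (adjusted p = 0.00665), while MGH3 fell by 2.39 ± 0.52 (adjusted p = 0.0457) and HCT fell by 1.66 ± 0.25 (adjusted p = 0.00787). Camera placed the secondary wall list lower (adjusted p = 0.00251; adjusted p = 0.227 with an estimated correlation), and its 3 members passed adjusted over the list alone and not over all genes. The tapetum list was higher (1 of 3 rose, 1 adjusted over the list alone; camera adjusted p = 0.00684; adjusted p = 0.412 with an estimated correlation), as was the photosynthesis list (none passed, 3 adjusted over the list alone; camera adjusted p = 0.00819; adjusted p = 0.412 with an estimated correlation). By the naming rule AT1G02813 rose by 5.74 ± 0.88 (adjusted p = 0.00974) and AT3G58060 fell by 4.36 ± 0.79 (adjusted p = 0.0234). Limma called 256 probe sets, 89 higher and 167 lower. The count was 72 and 21 without wild type bicellular replicates 1 and 2, 129 and 33 without wild type PMII replicates 1 and 2, 160 and 157 without wild type PMI replicates 1 and 2, 385 and 390 without ms35 PMII replicates 1 and 2, 60 without the variance trend and 412 from the arrays compared alone. AT5G07230 lost its call without wild type bicellular replicate 2 (adjusted p = 0.0874) or PMII replicate 2 (0.0625), within a range from 0.000426. HCT lost its call without wild type bicellular replicate 1 (0.0503), its replicate 2 (0.0926) or PMII replicate 2 (0.0579), without the variance trend (0.0616) and without the 2 arrays of highest GAPDH ratio (0.0504), within a range from 0.0021. AT1G02813 lost its call without wild type bicellular replicate 1 (0.0677), PMII replicate 1 (0.0673) or PMII replicate 2 (0.0545) and without the variance trend (0.0694), within a range from 0.000827. AT3G58060 lost its call without wild type bicellular replicate 1 (0.0895), its replicate 2 (0.198), PMII replicate 1 (0.0857) or PMII replicate 2 (0.0971), without a pseudocount (0.0747) and without the variance trend (0.0694), within a range from 0.00108. MGH3 lost its call in 13 of 23 settings, within 0.0081 to 0.265. Of these, 8 left out 1 array: wild type PMI replicates 1 and 2 (0.073 and 0.0723), bicellular replicates 1 and 2 (0.265 and 0.106), PMII replicates 1 and 2 (0.116 and 0.21) or ms35 PMI replicates 1 and 2 (0.0688 and 0.0685). The other settings were those without a pseudocount (0.0563), without a filter (0.0525), without the variance trend (0.152), with robust variances (0.106) and without the 2 arrays of highest GAPDH ratio (0.179).

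In ms35 the last step gave 68 calls by limma, 38 higher and 30 lower. AT5G07230 rose by 6.45 ± 0.75 (adjusted p = 0.0108), with mean tapetum list levels of 9.99 and 8.96 on the log2 scale in the ms35 arrays labelled PMII and 7.15 and 5.68 in those labelled bicellular. Camera placed the tapetum list higher (1 of 3 rose, 2 adjusted over the list alone; adjusted p = 0.0024; adjusted p = 0.412 with an estimated correlation), the photosynthesis list higher (none passed, 2 adjusted over the list alone; adjusted p = 0.0449; adjusted p = 0.463 with an estimated correlation) and the late pollen list lower (none passed, 2 adjusted over the list alone; adjusted p = 0.00819; adjusted p = 0.463 with an estimated correlation). The late pollen result rested on ms35 bicellular replicate 2, with a mean of 6.03 against 4.84 in replicate 1 and 4.25 and 4.70 in arrays labelled PMII. Its adjusted p was 0.219 without that array and 0.236 without both arrays of highest GAPDH ratio, within a range from 0.000831. The photosynthesis list had 0.493 without that array and 0.488 without both. It also did not pass without ms35 PMII replicate 1 (0.133), ms35 PMI replicate 2 (0.0547), wild type PMI replicates 1 and 2 (0.0564 and 0.056) or wild type PMII replicates 1 and 2 (0.0556 and 0.0518) and with a stricter filter (0.0608), within a range from 0.00177. The step correlated with that of wild type across genes (r = 0.40). It had 14 probe sets higher in both genotypes (0.205 expected) and 8 lower in both (0.304 expected), and differed between genotypes for 12. With only the arrays compared the step gave no calls by limma, as the closing section states. The 68 calls stated above came from the fit to all 12 arrays. This count rested on single arrays: none was called without ms35 PMII replicate 1 (limma; 1354 at an unadjusted p under 0.05), 579 without ms35 bicellular replicate 1, 12 without its replicate 2 and 508 without ms35 PMII replicate 2. It was 7 without either wild type PMI array, 40 without wild type bicellular replicate 2, 20 and 3 without wild type PMII replicates 1 and 2, and 4 without either ms35 PMI array. AT5G07230 lost its call without ms35 PMII replicate 1 (adjusted p = 0.287), without a pseudocount (0.0523) and without the 2 arrays of highest GAPDH ratio (0.0645, chosen after seeing the data), within a range from 0.000514.

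Of all 56 preset list tests, 15 passed with the preset correlation, none with an estimated correlation (camera; 5 at an unadjusted p under 0.05) and 6 with fry, which tests whether a list's genes move one way on balance. Across genes, the bicellular genotype effect had a slope of -0.118 on the wild type change from PMI to PMII (r = -0.209 across genes, which are not independent replicates). Slopes from single pairs of bicellular arrays ran from -0.272 to 0.0371, and without ms35 bicellular replicate 2 the slope was 0.0013.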

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

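Of the tests in this part, that of the array splits was chosen before its result was seen; those of the stage names, the chromosome segments and the size of the ms35 step were chosen after the values were seen.

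The averaged genotype effect gave 868 calls. Among 100 of the 108 possible splits of the arrays into 2 sets of 6 within stages, 1 split, the real one, gave as many. The highest of the others gave 148. Most of the other splits mix the genotypes within a group, so a genotype difference adds to their residual variance and lowers their counts. The result argues against chance assignment of arrays as the source, and with 108 possible splits it cannot exclude it.

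A difference between stages brought up 32 probe sets in the test of the interaction itself. The 8 named genes with the smallest p were AT3G27200 (adjusted p = 0.00155), AT3G06035 (0.00788), AT1G75280 (0.0187), AT1G44970 (0.0216), AT3G23840 (0.0307), ACLA-2 (0.0307), AT3G47800 (0.0355) and AT3G45850 (0.0414), the last 2 in a segment with an excess of genotype calls. Of these, AT3G06035 had effects of 1.35 at PMI and -1.80 at bicellular, and AT1G75280 -1.97 at bicellular and 0.80 at PMII. All 8 lost the call without the variance trend, and ACLA-2 and AT3G45850 lost it in 14 of 23 settings each. AT3G47800 lost it in 11 settings, AT1G44970 in 8, AT3G23840 in 7, AT1G75280 in 6, AT3G06035 in 3 and AT3G27200 in 1.

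The stage markers ran against the stage names. From arrays labelled PMI to those labelled PMII the late pollen list had a median change of -2.33 in wild type and -1.44 in ms35, and the tapetum list of 6.60 and 7.04, the values that an exchange of the names PMI and PMII would give. A single mislabelled array is argued against, since the array labelled PMI had the higher late pollen mean in all 8 pairs of arrays of 1 genotype, and so is array scaling, under whose alternatives the median was at most -1.48. A lower share of pollen RNA alone is argued against because the tapetum list rose by 3.70 more than the photosynthesis list (SD 0.522 over 8 pairs, which share arrays). Of the 3 tapetum genes, SHT rose by 7.26 in wild type and 7.04 in ms35, and AT5G07230 by 6.60 and 7.46. The latter's size depends on the pseudocount, with signals of 0.65 to 3.87 in arrays labelled PMI. AMS rose by 2.41 and 1.22, against 2.12 and 1.64 for the photosynthesis gene PRK, so the argument rests on the other tapetum genes. An exchange of names, or a collection of flower buds whose order differed from the stage names, may account for the pattern and stays open: the array titles carry sets of numbers that rise from PMI to PMII, whose meaning the labels do not give; an exchange made alike in both genotypes would leave the genotype effects within a stage as they are.

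Genotype calls were gathered in segments of the genome. Over bins of 5000 locus numbers, the chi-square of the averaged effect divided by its degrees of freedom was 3.09, none of 1000 permutations reached it (0; highest 1.59), and 5 bins held 106 of 436 called loci, 11.7% of their loci against 4.08% elsewhere. Neighbouring genes that change together whatever the comparison are argued against by a value of 0.877 for the more numerous calls of the first wild type step, and linkage to MYB26 by 4.17% called on its chromosome arm (upper 95% bound 5.51), against 4.85% overall. Segments of another accession in 1 genotype could give such a pattern, since the labels name the wild type source Glabra, its arrays Ler and the ms35 background Ler-0; 44.3% of calls inside the bins were higher in ms35 and 44.8% elsewhere (Fisher's exact test, two-sided, p = 1), an even split that excludes nothing, so this stays open. Without the named probe sets of these bins, 735 calls were left.

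The step from PMI to bicellular gave 434 calls in ms35 (818 without ms35 bicellular replicate 2, 41 without its replicate 1, 33 without ms35 PMI replicate 2, 248 and 244 without wild type bicellular replicates 1 and 2); in wild type it gave 2977 (1686 and 1401 without wild type PMI replicates 1 and 2, 1706 and 1056 without wild type bicellular replicates 1 and 2). The array ms35 bicellular replicate 2 lay nearer to the arrays labelled PMI than replicate 1 did, at -19.0 against 28.3 on the first principal component, with a late pollen mean of 6.03 against 4.84 and a tapetum mean of 5.68 against 7.15. Noisier ms35 arrays alone are argued against by the spread of the changes after removal of replicate noise, estimated over all 6 groups together. The spread in ms35 was 0.611 times that of wild type. With any 1 array of these stages left out it ran from 0.451, without ms35 bicellular replicate 1, to 0.798, without its replicate 2. Tested directly, the step differed between genotypes for 16 probe sets. The genotype effect had a mean slope of 0.165 on the wild type step at PMI and of -0.166 at bicellular, but a smaller step in ms35 itself puts the second below the first, so these slopes decide nothing. Whether ms35 anthers were at another point of the wild type course under the same stage name, or changed less between the stages, cannot be told apart.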

How the results depend on the processing

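The alternatives over the bicellular and PMII stages alone, without the enriched segments and without the 2 arrays of highest GAPDH ratio were chosen after seeing the data. The averaged effect stayed within 1.5 times of its 868 calls under every other alternative, from 588 without wild type bicellular replicate 1 to 837 without ms35 bicellular replicate 2 among the single arrays, except for 374 with a 2-fold minimum and 516 over the bicellular and PMII stages alone, with the variance still taken from all arrays; it was 828 without the chromosome 3 arm that carries MYB26. "Only the arrays compared" does not apply to it or to the interaction.

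Leaving out single arrays, which leaves 1 array in a group that is assumed to vary like the others, gave 127 to 359 calls at PMI, 97 to 284 at bicellular, 45 to 178 at PMII, 1056 to 3159 and 21 to 390 for the wild type steps, 33 to 818 and 0 to 579 for the ms35 steps, 6 to 56 for the interaction and 10 to 19 list tests. The stage shift ran from -0.236 to 0.0013, the latter without ms35 bicellular replicate 2 and of the opposite sign.

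The replicate numbers were not taken to pair the samples: deviations of same-numbered arrays correlated from -0.126 to 0.182, over 0.1 in 4 of 15 pairs of groups. With the replicate block the ms35 steps gave 653 and 181 calls and no other count moved by over 1.5 times. Without the variance trend the counts were 179 (PMI), 57 (PMII), 60 (wild type last step), 111 and 17 (ms35 steps) and 0 (interaction). The last ms35 step gave 1 call without a pseudocount, 195 with a larger pseudocount, 37 without a filter, 39 with a stricter filter, 113 with robust variances and 3 with array weights, which gave 245 for the first ms35 step. The interaction gave 58 with the larger pseudocount and 57 with robust variances. From the arrays compared alone the counts were 159 (bicellular), 96 (PMII), 412 (wild type last step), 1 and 0 (ms35 steps; limma, 2224 at an unadjusted p under 0.05 for the last). Without the 2 arrays of highest GAPDH ratio they were 59 (PMII), 101 (wild type last step), 878 and 0 (ms35 steps; 1716 at an unadjusted p under 0.05) and 17 (interaction). At an adjusted p under 0.10 they were 603 (PMI), 253 (PMII), 634 (wild type last step), 934 and 532 (ms35 steps) and 64 (interaction). List tests gave 0 with an estimated correlation and 6 with fry. Fewer arrays, fewer probe sets or another threshold define several of these settings; otherwise the cause was not tested.

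Of 281 results for named genes, called family members and plastid genes, 101 kept their call in every setting run, 180 lost it in at least 1 and none reversed. These results had been chosen for passing the threshold in the same arrays, so the lack of reversals says little. Those of the interaction had no direction that could reverse. Genes with a mean signal near the pseudocount of 2.23 in 1 genotype have fold changes that depend on it.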

Other observations

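The plastid genes were singled out after their values were seen; the families were fixed earlier. Other gene families, defined from symbols before any contrast was computed, held single members that changed between genotypes. The expansin EXPA4 rose by 1.22 ± 0.25 on the log2 scale in ms35 (averaged effect, limma adjusted p = 0.0125), while EXLA1 fell by 0.95 ± 0.20 (adjusted p = 0.0155). Of 27 UDP-glycosyltransferases 2 rose and 4 fell, UGT74F1 by 1.90 ± 0.37 (adjusted p = 0.00933), with an adjusted p of at most 0.0395 over the alternatives; the family as a whole did not pass camera (adjusted p = 0.958). Of these 6 genes, 3 lost their call in some of 23 settings. UGT85A3 lost it in 15 (adjusted p from 0.0263 to 0.167), among them each single array left out other than wild type PMII replicate 1 and ms35 PMI replicate 2. GT72B1 lost it in 10 (0.0152 to 0.089), among them each single array left out other than wild type bicellular replicate 1, wild type PMII replicate 2, ms35 PMI replicate 2 and ms35 bicellular replicate 1. UGT76E11 lost it without wild type bicellular replicate 1 (0.052) or ms35 PMII replicate 1 (0.0569), within a range from 0.00842. EXPA4 lost its call without the variance trend (adjusted p = 0.0519; range from 0.00159), and EXLA1 there (0.0661; range from 0.00142) and without wild type PMI replicate 2 (0.0558). EXLA1, UGT85A3 and UGT76E11 lie in segments with an excess of genotype calls. TBL34, of a family of wall polysaccharide acetyltransferases, fell by 1.88 ± 0.38 (adjusted p = 0.0128) and TBL26 rose by 1.09 ± 0.17 (adjusted p = 0.00259); TBL34 lost its call without wild type bicellular replicate 1 (0.0518; range from 0.00373). Of 200 family tests, 4 passed with the preset correlation and none with an estimated one or with fry; these tests were not repeated under the other settings. In wild type, PLIM2a and AtVEX1, genes of mature pollen, fell by 5.28 ± 0.91 and 4.66 ± 0.78 between arrays labelled PMI and bicellular, and 4 of 9 added pollen genes fell (camera adjusted p = 0.026; adjusted p = 0.952 with an estimated correlation), as did 3 of 4 late embryogenesis abundant genes (camera adjusted p = 0.0359; adjusted p = 0.952 with an estimated correlation). Among these, TUA1 lost its call without wild type bicellular replicate 1 (0.0604), its replicate 2 (0.0642) or wild type PMI replicate 2 (0.109), within a range from 0.00577. LEA4-5 lost it without wild type PMI replicate 1 (0.0718), its replicate 2 (0.0764) or wild type bicellular replicate 2 (0.135), within a range from 0.00161.

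Of 67 tested plastid-encoded genes, 5 were called for the averaged genotype effect, beside 868 of all 16464 probe sets. The plastid share was not tested against the share of all probe sets. The probe set of ccsA, a gene needed for cytochrome c assembly, had a log2 difference of -2.32 ± 0.10 between ms35 and wild type (adjusted p = 1.30e-07), with close values at the stages labelled PMI (-2.31), bicellular (-2.39) and PMII (-2.25). The difference was -1.79 ± 0.18 for the ribosomal protein gene rpl14 (adjusted p = 0.000113), -0.87 ± 0.13 for psbK, 0.83 ± 0.16 for rps4 and -0.55 ± 0.15 for psbI (adjusted p = 0.0491). The last lost its call in 16 of 23 settings (adjusted p from 0.0054 to 0.158), among them each single array left out other than ms35 PMII replicate 2. Since the labels do not settle whether both lines share an accession, a difference in transcript level and a difference in how well the probes match were not separated here. The median of the plastid genes other than ccsA and rpl14 was -0.05.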
